A study of Mus musculus with 13 samples.

How the data were processed

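The deposited table held UMI counts per gene and cell from Drop-seq of dissociated medial amygdala, with 6 male and 7 female libraries of naive C57BL/6J mice. In Drop-seq each cell shares a droplet with a barcoded bead, and the UMI on each captured mRNA lets copies made in amplification be counted as 1 molecule. Mice were aged 8 or 9 weeks (8 weeks in male replicates 3 and 5 and female replicate 3), were kept on a reversed light cycle and had been housed alone for at least 1 day. Per the submitters' processing notes, reads were handled with bcl2fastq 2.17.1.14 and STAR 2.5.0a on the mm10 build. How UMIs were collapsed and how cells were chosen is not given in the sources used here. The deposited values were counts, as whole numbers with differing totals per cell, with no normalization. The cell names carried the library and the class that the authors gave the cell: astrocyte, oligodendrocyte, oligodendrocyte precursor, newly formed oligodendrocyte (named there as in between precursor and oligodendrocyte), microglia, endothelial cell, mural cell or neuron.

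The table held 16961 genes and 43388 cells. Cells with at least 500 detected genes were kept, and 281 doublets called by Scrublet in each library (1.13%) were removed. The filter on mitochondrial transcripts had no effect because the table held 0 mitochondrially encoded genes. This left 24527 cells, 1149 to 2908 per library. The filter removed neurons more than other classes, since 3649 of 10166 deposited neurons had at least 500 genes, and 3615 remained after doublets were removed. Kept UMIs per library were 3718151 to 7874074. A UMI count of 0 allows up to 3 molecules over the group, and this floor and the counting intervals (95%, conditional on the total) cover counting error only.

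Neurons were clustered on counts scaled to 10000 per cell and log-transformed, with 2000 variable genes, 30 principal components, 15 neighbours and Leiden resolution 1 (0.5 and 2 as alternatives), leaving out Xist, Tsix and the Y-linked genes. Xist_exon1, a separate entry of the table that is not in the fixed list, was left out with Xist here and wherever genes were counted without the sex-linked ones. Leading genes were the 10 with the largest fold against the other neurons among those detected in at least 25% of a cluster's cells, with 5 CPM added to both sides. A cluster was called GABAergic-like or glutamatergic-like when its transporter (Slc32a1 or Slc17a6) was detected in at least 50% of its cells and the other in under 20%. Its leading genes also had to hold no more markers of any non-neuronal class than of its own class and of neurons together. This naming rule was set after the clusters were seen and before any comparison of the sexes within them.

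Counts were summed per library within a class, so the library was the replicate. A class was tested where at least 3 libraries of each sex held 10 or more of its cells. The sexes were compared with the quasi-likelihood F test of edgeR 4.0.16 (TMM scaling, filterByExpr, robust dispersion) in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. The standard error of a log2 difference is its size divided by the square root of F. Class by sex terms and differences between neuron classes were fitted the same way with the library as a block. CPM of tested genes are TMM-scaled means over libraries, and clock genes per library are TMM-scaled too. CPM of genes below the expression filter, in pooled clusters and of libraries that stood apart are unscaled CPM of all UMIs of the class. Gene lists and cell type markers with at least 5 tested genes were tested with camera of limma 3.58.1 at its preset correlation of 0.01, adjusted over the lists of a class, and again with an estimated correlation, and with fry. "Adjusted over the list alone" means Benjamini-Hochberg adjustment over the tested members of that list. Cell shares were compared by an exact two-sided permutation test over all 1716 assignments of sex to libraries.

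The tests, the 19 gene lists, the cell type markers, the rule for named genes and all alternatives but 2 were fixed before the data were examined. Named genes were Xist, Ddx3y, Eif2s3y, Kdm5d and Uty, up to 10 genes per direction with the smallest adjusted p among those past the threshold with a mean of at least 20 CPM (up to 5 in mural cells and newly formed oligodendrocytes), list members past the threshold, and 13 hormone and peptide genes in neurons, 1 of which is not reported here. Tsix, Gpc3, Arntl, Ahnak and members of lists that passed only when adjusted over the list alone were named after their values had been seen. Genes listed under older symbols were used under the table's own (Gm129 for Ciart, Drd1a for Drd1, Arntl for Bmal1). Gene positions came from GENCODE M21 on GRCm38, the assembly that mm10 names, with 1-based starts. Of the table's symbols 15925 matched directly, 755 matched by an older symbol, 35 fell in several places and 246 had no match. The counts are per gene, so no position within a gene was measured.

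Alternatives were DESeq2 1.42.0 size factors in edgeR, the DESeq2 Wald test, limma voom with sample quality weights, no gene filter, no cell filter or at least 800 genes per cell, doublets kept, age or median UMIs per cell as a covariate, the replicate number as a block, equal cells and UMIs per class, genes counted without Xist (with Xist_exon1), Tsix and the Y-linked genes, classes from marker UMIs, other clustering resolutions and, for shares, 9-week libraries alone and centred log ratios. Each library was left out in turn. Added after seeing the data were the GABAergic-like class with cluster 10, and both neuron classes with the parts of cluster 1 that passed the naming rule when clustered alone. On simulated counts with 200 changed genes, the test recovered 99% of the genes changed by log2 1 in GABAergic-like neurons and 95% in glutamatergic-like neurons, and 74% for the class by sex term. At log2 2 it recovered 100% in each of these. These simulations tested 2713, 2951 and 3463 genes, fewer than the 4753, 5298 and 6012 genes of the real tests. Recovery of the genes left out of the simulations was not measured. The comparisons of the real data were repeated on up to 100 other splits of the 13 libraries into groups of 6 and 7, drawn with a fixed seed, with the real split among them. For neuron clusters the splits were of the libraries fitted in each cluster, into groups of the same sizes as the sexes there. The clustering used scanpy 1.11.5 in Python 3.11.15.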

Results

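Single-cell transcriptomes of the medial amygdala were compared between naive male and female mice of the inbred strain C57BL/6J. The medial amygdala is a forebrain region that takes part in social behaviour, and the series is about how it controls parenting differently in the sexes. Cells were dissociated with Act-seq, a protocol that blocks transcription during dissociation, and captured by Drop-seq, which counts mRNA molecules (UMIs) per cell. There were 6 male and 7 female libraries. Male replicates 3 and 5 and female replicate 3 came from mice aged 8 weeks, and the other libraries from mice aged 9 weeks. The labels name separate samples but not separate animals, so the p-values measure the spread between these libraries, which may be technical.

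The deposited table held 43388 cells and 16961 genes, and 24527 cells (11542 male, 12985 female) were kept. Kept UMIs per library ranged from 3718151 in female replicate 1 to 7874074 in male replicate 4, with 5523627 ± 1390344 (SD, n = 6) in males and 5037147 ± 793109.6 (SD, n = 7) in females. The median cell held 1745.5 to 2434 UMIs, depending on the library. The authors' class names divided the kept cells into 6445 astrocytes, 4163 oligodendrocyte precursors, 3887 oligodendrocytes, 3727 microglia, 3615 neurons, 1463 endothelial cells, 764 mural cells and 463 newly formed oligodendrocytes. Below, levels are CPM (the UMIs of a gene scaled to the UMIs of the library, as in edgeR) as mean ± SD over 6 male and 7 female libraries, log2 differences are male minus female ± SE, and adjusted p-values are those of edgeR.

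Over all cells, the sex-linked transcripts matched the labels in every library. Xist, the non-coding RNA that silences one X chromosome in female cells, stood at 1219.9 ± 67.8 CPM in females and 0.305 ± 0.240 CPM in males (edgeR adjusted p = 2.3e-18, chromosome X, 103460366 to 103483254). The Y-linked Eif2s3y, which encodes a translation initiation subunit, stood at 159 ± 13.9 CPM in males and had 0 UMIs in females, so it was at least 1886-fold higher from a floor of 3 UMIs over the female group (chromosome Y, 1010543 to 1028847). Ddx3y stood at 129 ± 14.1 CPM in males and 0.170 ± 0.169 CPM in females. Kdm5d and Uty had 3 UMIs each in females, which gives ratios of 479 (95% counting interval 163 to 2324) and 437 (149 to 2122). Tsix stood at 131 ± 29.9 CPM in females and 0.265 ± 0.186 CPM in males, but it overlaps Xist on the opposite strand and the strand used in counting is not given in the sources used here, so its value is uncertain.

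Genes on the X chromosome known to escape inactivation were higher in females over all cells: 3 of 5 passed the test, and all 5 passed when adjusted over the list alone. Kdm6a, a histone demethylase, stood at 78.1 ± 8.55 CPM in females and 51.6 ± 4.82 CPM in males (log2 -0.59 ± 0.08, edgeR adjusted p = 0.00198, chromosome X, 18162575 to 18279936). The list passed camera (median log2 -0.42, adjusted p = 2.6e-09, and 9.1e-04 with an estimated correlation). In total 85 genes differed, 18 higher in males and 67 higher in females, of 14314 tested, and 2000 had an unadjusted p under 0.05. Leaving out the sex-linked list (Xist with its separate entry Xist_exon1, Tsix and the Y-linked genes) left 78. Genes that microglia and macrophages express stood among those higher in females, such as Tspo, a mitochondrial membrane protein (40.5 ± 7.45 against 23.1 ± 4.38 CPM, adjusted p = 0.0149), Crybb1 (57.7 ± 10.9 against 36.5 ± 4.07, adjusted p = 0.0177), P2ry13, a purine receptor (119.5 ± 10.4 against 88.9 ± 8.60, adjusted p = 0.0187), and Cd68, a lysosomal protein (86.5 ± 9.65 against 59.7 ± 8.15, adjusted p = 0.0187). Without female replicate 6 the calls of all 4 were lost (edgeR adjusted p = 0.0501 for Tspo, 0.0556 for the others), and without female replicate 3 those of P2ry13 and Cd68.

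The set of genes called over all cells depended on single libraries. The count of 85 became 10 without female replicate 6, 13 without female replicate 3, 33 without female replicate 4, 36 without female replicate 5, 40 without female replicate 7 and 234 without female replicate 2. It became 39 without male replicate 1, 43 without male replicate 2, 36 without male replicate 3 and 37 without male replicate 6. The clock genes Cry1 (log2 0.69 ± 0.14, edgeR adjusted p = 0.0328) and Per2 (0.90 ± 0.19, 0.0438) and the clock output gene Tef (0.49 ± 0.11, 0.0449) were higher in males, and their calls were lost without 7, 11 and 11 of the 13 libraries (edgeR adjusted p up to 0.0812, 0.101 and 0.104).

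Markers of whole cell types also moved over all cells, where the makeup of the cells was free to vary. Microglia markers were lower in males (12 genes, median log2 -0.36, camera adjusted p = 1.2e-12), as were markers of endothelial cells (12, -0.46, 6.6e-09), vascular leptomeningeal cells (10, -0.54, 0.00416), perivascular macrophages (9, -0.54, 0.0154) and mural cells (11, -0.38, 0.0271). Neuron markers (12, 0.40, 3.2e-05) and GABAergic markers (9, 0.43, 4.6e-04) were higher in males. None of these 7 calls held with an estimated correlation, where the adjusted p was 0.488 for microglia, 0.490 for endothelial cells, 0.513 for leptomeningeal cells, 0.642 for macrophages and mural cells, and 0.4998 for both neuron lists. The other lists had medians of 0.31 for glutamatergic neurons (adjusted p = 0.171), 0.03 for astrocytes (0.469), 0.08 for tanycytes (0.469), 0.07 for choroid plexus (0.893), -0.0046 for neuroblasts (0.893), -0.13 for ependymal cells (0.469), -0.09 for newly formed oligodendrocytes (0.469), -0.07 for oligodendrocytes (0.171), -0.07 for oligodendrocyte precursors (0.295) and -1.27 for blood cells (0.174).

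Of the gene lists, synaptic vesicle and release genes (23 genes, median log2 0.38, camera adjusted p = 1.1e-09), GABA and glutamate receptor subunits (25, 0.26, 5.5e-07), potassium channels (23, 0.17, 4.3e-05) and clock genes (16, 0.30, 1.3e-05) were higher in males over all cells. Higher too were neuropeptides (24, 0.33, 0.00216), axon guidance and cell adhesion genes (36, 0.13, 0.00427), neuropeptide receptors (21, 0.31, 0.00449), genes known to differ by sex (7, 0.48, 0.0102) and hormone receptors with steroid enzymes (9, 0.22, 0.0445). Ribosomal proteins (108, -0.20, 1.0e-12) and immediate early genes (20, -0.22, 0.00216) were lower. With an estimated correlation none of these 11 kept its call (adjusted p = 0.238 to 0.524). Neurons gave 20.4% ± 6.93 of UMIs in males and 14.8% ± 4.13 in females. Lists of genes that neurons express could therefore move over all cells with makeup alone, which was not tested for these lists. Heat-shock genes (14, -0.0052, 0.560), oxidative phosphorylation genes (90, -0.02, 0.530), cortical genes (6, 0.08, 0.530) and striatal genes (6, 0.10, 0.530) did not pass.

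The neurons were clustered to tell transmitter types apart, since the study asks which medial amygdala neurons differ by sex. Of 17 clusters, 5 were GABAergic-like by the vesicular GABA transporter Slc32a1, with 702 male and 622 female cells (37.4% and 35.8% of neurons). Another 5 were glutamatergic-like by the vesicular glutamate transporter Slc17a6, with 584 and 591 cells (31.1% and 34.0%). Slc32a1 was seen in 68.5% to 94.5% of the cells of the GABAergic-like clusters, against 0.559% of astrocytes, whose median depth of 1810 UMIs was close to the 1755 of neurons. Among the GABAergic-like clusters, cluster 5 was led by Npy, Moxd1 and Igfbp4, cluster 7 by Gpc3 and N4bp2, cluster 8 by Ucn3 and Nts, cluster 9 by Npnt, Cnr1 and Kit, and cluster 14 by Slc32a1, Vgf and Nrxn3. Among the glutamatergic-like clusters, cluster 2 was led by Nhlh2, Trp73 and Ndnf, cluster 4 by Slc17a7 and Angpt1, clusters 6 and 11 by Adcyap1 and Bdnf, and cluster 12 by Trh, Abi3bp and C1ql3. The other 7 clusters, with 31.6% of male and 30.1% of female neurons, stayed out of both classes. Clusters 3, 15 and 17 were led by astrocyte (Slc1a3, Gja1), oligodendrocyte (Mobp) or microglia (Ctss, C1qa) genes. Cluster 1 mixed both transmitter types at a median of 14250 UMIs, and clusters 13 and 16 had neither transporter in most cells. Cluster 10 (Scn10a, Six3) met the transporter rule of the GABAergic-like class, with Slc32a1 in 76.8% and Slc17a6 in 1.22% of its cells. It was left out because its leading genes held 1 tanycyte marker (Col23a1) and 0 markers of its own class or of neurons. Cluster 4 also held 1 tanycyte marker, but with 1 marker of its own class, and was kept. The sizes of the classes were not compared, because Npnt, Bdnf and Gpc3, which lead clusters, are among the genes described next.

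In GABAergic-like neurons Npnt, which encodes the extracellular matrix protein nephronectin, was lower in males. It stood at 34.2 ± 18.7 CPM in 6 male and 128 ± 55.1 CPM in 7 female libraries (log2 -1.89 ± 0.32, edgeR adjusted p = 0.00329, chromosome 3, 132881745 to 132950291), and all 7 female libraries lay above the male median. Most of its UMIs came from cluster 9, which it leads, at 149 CPM in the pooled male and 616 CPM in the pooled female cells of that cluster. The other 3 genes that differed were Xist, Tsix and Eif2s3y, of 4753 genes tested, and 232 had an unadjusted p under 0.05. Prolactin receptor (Prlr) stood at 351 ± 126 CPM in males and 299.6 ± 77.3 CPM in females (log2 0.23 ± 0.25, edgeR adjusted p = 0.998). It did not pass the test, nor did the peptide genes Tac1 (0.35 ± 0.27), Sst (-0.42 ± 0.36), Cartpt (0.54 ± 0.28), Npy (-0.23 ± 0.44), Cck (0.32 ± 0.51) or Penk (0.15 ± 0.27). The call of Npnt was lost without male replicate 5 (edgeR adjusted p = 0.0553), with limma voom (0.167) and with no filter on cells (0.233).

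Glutamatergic-like neurons differed in Bdnf, the neurotrophin that supports synapses. Bdnf stood at 798 ± 229.5 CPM in 6 male and 423 ± 63.3 CPM in 7 female libraries (log2 0.93 ± 0.17, edgeR adjusted p = 0.00616, chromosome 2, 109674700 to 109727007), and all 6 male libraries lay above the female median. The pooled cells of cluster 6 held 957 CPM in males and 541 CPM in females, and those of cluster 11 held 1377 and 1075 CPM. These 2 clusters, which Bdnf leads, made up 107 and 220 of the 584 male cells of the class but 65 and 181 of the 591 female cells. The value over the class may therefore hold a difference in makeup as well as in level, and the 2 were not separated. Bdnf was not among the genes called within either cluster. The other 4 genes that differed were Xist, Tsix, Ddx3y and Eif2s3y, of 5298 tested, and 160 had an unadjusted p under 0.05. Pdyn, the gene of dynorphin, stood at 99.4 ± 49.7 and 54.7 ± 34.6 CPM (log2 0.82 ± 0.33, adjusted p = 0.9997). Cck (-0.20 ± 0.39), Penk (0.28 ± 0.19), Tac1 (0.58 ± 0.52), Sst (0.25 ± 0.89), Cartpt (-0.25 ± 0.27) and Prlr (-0.04 ± 0.31) also stayed above the threshold. The cytosolic ribosomal protein list was lower in males (58 genes, median log2 -0.21, camera adjusted p = 2.0e-06), but not with an estimated correlation (adjusted p = 0.840). The call of Bdnf was lost without male replicate 5 (edgeR adjusted p = 0.0821) and under 4 of 13 other settings, where its adjusted p reached 0.378.

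Whether the sex difference itself differed between the neuron classes was tested with a class by sex term, with the library as a block. Of 6012 genes, 2 passed, and 273 had an unadjusted p under 0.05. Gpc3, a cell-surface heparan sulphate proteoglycan, had a log2 sex difference of -0.37 ± 0.17 in GABAergic-like and 1.57 ± 0.35 in glutamatergic-like neurons, neither past the threshold on its own (edgeR adjusted p = 0.986 and 0.0862). The difference between them was -1.89 ± 0.33 (edgeR adjusted p = 0.00108). In cluster 7, which Gpc3 leads, the pooled male and female cells held 193 and 189 CPM. Npnt had a difference of -2.58 ± 0.53 (edgeR adjusted p = 0.0277), and Bdnf one of -1.66 ± 0.37 that did not pass (0.173). DESeq2 with the same design called 0 genes, with 125 at an unadjusted p under 0.05. The count was 1 without any of female replicates 2 and 4 and male replicates 2, 5 and 6, and 4 without male replicate 1.

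Of the gene lists fixed before the data were examined, 0 passed camera in GABAergic-like neurons, with 1 of 10 at an unadjusted p under 0.05. Axon guidance and cell adhesion genes had a median log2 of -0.05 (33 genes, camera adjusted p = 0.324), and 4 of them were lower in males when adjusted over the list alone: Ntng1 (-0.72), Epha7 (-0.52), Robo1 (-0.56) and Cdh8 (-0.41). Synaptic vesicle and release genes had a median of 0.06 (20, 0.324), GABA and glutamate receptor subunits -0.03 (23, 0.537), heat-shock genes 0.13 (9, 0.537), nuclear oxidative phosphorylation genes 0.05 (74, 0.611), neuropeptides -0.05 (16, 0.628), neuropeptide receptors -0.04 (11, 0.628, with a mean of 0.08), potassium channels -0.02 (20, 0.718), clock genes 0.02 (5, 0.718) and ribosomal proteins -0.06 (48, 0.718). With an estimated correlation the adjusted p was 0.842 for each, and with fry it was 0.787. Lists with under 5 tested members were not given to camera. Of the X-linked genes that escape inactivation, Kdm6a (-0.91) and Ddx3x (-0.41) were measured and passed only when adjusted over the list alone (adjusted p = 0.0150 and 0.0460). None of the 3 measured hormone receptor and steroid enzyme genes, 3 genes known to differ by sex (Ecel1 0.64, Nnat -0.34, Pak3 0.25), 2 immediate early genes (Jund -0.33, Egr1 -0.11), 4 striatal genes (Pde10a 0.30, Drd1a -0.23) or 2 cortical genes (Lmo3 0.26, Nptx1 0.22) passed, also when adjusted over each list alone. Hypothalamic list genes and mitochondrially encoded genes were not analysed here in this class.

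In all neurons, the 6 genes that differed were Xist (at least 2248-fold higher in females), Tsix, Ddx3y, Eif2s3y, Kdm5d and Uty, so 0 were outside the sex-linked list. DESeq2 called 7 genes and limma voom 6 with that list counted, and edgeR gave 591 of 9635 genes an unadjusted p under 0.05. The estrogen receptor Esr1 (6.20 ± 2.06 and 9.14 ± 8.85 CPM), the progesterone receptor Pgr (11.002 ± 4.38 and 8.36 ± 4.82) and aromatase Cyp19a1 (7.95 ± 4.23 and 3.66 ± 2.62), which makes estrogen from testosterone, were below the expression filter, with 39 and 46, 73 and 42, and 51 and 20 UMIs, and were not tested. Prlr (0.05 ± 0.20), Oxtr (-0.13 ± 0.29), Tac1 (0.49 ± 0.32), Sst (-0.07 ± 0.50), Cartpt (0.38 ± 0.26), Npy (0.30 ± 0.60), Cck (-0.37 ± 0.35), Penk (0.09 ± 0.23) and Pdyn (0.19 ± 0.25) did not pass. Of the lists in all neurons, ribosomal proteins (94 genes, median log2 -0.19, camera adjusted p = 3.1e-07), axon guidance genes (36, -0.14, 3.9e-04) and GABA and glutamate receptor subunits (24, -0.11, 0.00734) were lower, and oxidative phosphorylation genes (86, 0.08, 0.00734), synaptic vesicle genes (23, 0.14, 0.00734) and genes known to differ by sex (6, 0.45, 0.00734) higher in males. With an estimated correlation their adjusted p was 0.667, 0.629, 0.746, 0.753, 0.474 and 0.549. Astrocyte (median log2 -0.59, camera adjusted p = 0.00262), microglia (-0.57, 0.00262) and oligodendrocyte markers (-0.40, 0.0336) within neurons were lower in males, but not with an estimated correlation (adjusted p = 0.366, 0.307 and 0.366). All neurons here included clusters 3, 15 and 17, which glial genes lead, with 268, 121 and 15 of the 3615 cells. Cluster 3 made up 0% of the neurons of male replicate 3 and 18.7% of those of male replicate 1. How far these cells moved the results in all neurons was not tested.

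Single neuron clusters gave 15 calls over the 11 clusters tested, of which 4 were outside the sex-linked list. Penk, the gene of enkephalin, was lower in males in cluster 4 (10 UMIs in 36 cells of 3 male and 108 UMIs in 61 cells of 5 female libraries, log2 -2.63 ± 0.57, edgeR adjusted p = 0.0469). The male libraries were replicates 3, 4 and 5, of which 3 and 5 were aged 8 weeks, while these females were all aged 9 weeks. Age can therefore hardly be told apart from sex in this fit, and no male library could be left out of it. The call of Penk was lost without female replicate 2 or 4 (edgeR adjusted p up to 0.122), 2 of the 5 fits possible with a library left out. Pafah1b1, a dynein regulator, was higher in males in cluster 7 (567 ± 109 against 315 ± 74.9 CPM, log2 0.85 ± 0.19, edgeR adjusted p = 0.0277). Rbm25 in cluster 6 (-0.97 ± 0.21, 0.0331) and Srrm1 in cluster 2 (0.80 ± 0.19, 0.0409), both of them splicing factors, also passed. The calls of Pafah1b1, Rbm25 and Srrm1 were lost in 6 of 13, 4 of 5 and 9 of 11 such fits (edgeR adjusted p up to 0.172, 0.1304 and 0.165), and that of Xist in cluster 12 without male replicate 6 (0.0975). The count of 15 became 9 without female replicate 3, female replicate 5 or male replicate 6, 8 without male replicate 1 and 7 without male replicate 3, but only 8, 8, 10, 6 and 5 of the 11 clusters could then be fitted, so part of each drop is in clusters no longer tested.

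Astrocytes differed in 113 genes, 50 higher and 63 lower in males, of 9779 tested. Genes higher in males were Lifr, the receptor of leukaemia inhibitory factor (175 ± 30.4 against 110.0 ± 17.1 CPM, log2 0.63 ± 0.10, edgeR adjusted p = 1.6e-04), and the hypoxia-inducible factor Hif3a (46.5 ± 14.8 against 20.7 ± 3.90, 1.17 ± 0.19, 1.7e-04). Higher as well were the glutamate receptor subunit Gria2 (1993 ± 235 against 1468 ± 160.0, 0.44 ± 0.08, 3.1e-04) and Dio2, the deiodinase that activates thyroid hormone (142 ± 41.2 against 88.7 ± 7.60, 0.69 ± 0.13, 0.00161). Extl1 (1.10 ± 0.22), Ilk (0.49 ± 0.10), Slc25a33 (0.49 ± 0.10) and the potassium channel Kcnn2 (0.48 ± 0.10) were also higher in males. Genes lower in males were the X-linked RNA helicase Ddx3x (181 ± 17.7 against 273 ± 7.08, -0.59 ± 0.08, 2.3e-06) and Kdm6a (-0.74 ± 0.15, 0.00385). Gpr179 (29.4 ± 6.93 against 60.7 ± 14.9, -1.05 ± 0.16, 2.3e-05), Plat, the tissue plasminogen activator (74.3 ± 19.98 against 119.8 ± 14.8, -0.70 ± 0.12, 3.6e-04), and the acyl-CoA binding protein Dbi (2905 ± 379.5 against 3889 ± 349.7, -0.42 ± 0.08, 6.1e-04) were lower as well. So were Ppp1r1b, which encodes the phosphatase inhibitor DARPP-32 (-0.64 ± 0.12, 8.6e-04), and Ahnak (-0.94 ± 0.17), Rnft1 (-0.81 ± 0.15) and Dkk3 (-0.48 ± 0.09). Each of these calls held without any single library. The escape list was lower in males (5 genes, median log2 -0.60, camera adjusted p = 6.8e-08, and 6.4e-04 with an estimated correlation).

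Of the other lists in astrocytes, clock genes were higher in males (16 genes, median log2 0.18, camera adjusted p = 0.00285, and 0.294 with an estimated correlation), with Per2 (0.82 ± 0.18, edgeR adjusted p = 0.00723) and Tef (0.38 ± 0.09, 0.0155) past the test. Without male replicate 1 the adjusted p was 0.0689 for Per2 and reached 0.0966 for Tef, whose call was also lost without male replicate 2 or 4. Ribosomal proteins (89 genes, -0.13, 5.1e-07), oxidative phosphorylation genes (86, -0.06, 0.00285) and heat-shock genes (12, -0.10, 0.0308) were lower in males, and with an estimated correlation their adjusted p was 0.294, 0.406 and 0.318. The immediate early genes Fos (-0.80 ± 0.20) and Jund (-0.46 ± 0.12) and the chaperone Hsp90aa1 (-0.37 ± 0.09) were lower in males, calls each lost without 7 of the 13 libraries. Markers of microglia (-0.34, adjusted p = 0.0172) and of astrocytes (-0.11, 0.0172) were lower and those of neurons higher in males (0.11, 0.0172), with 0.250 for each with an estimated correlation. The count of 113 became 64 without male replicate 1, 68 without male replicate 2, 66 without male replicate 6 and 205 without male replicate 5.

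In oligodendrocytes, clock genes were higher in males. The list passed camera (10 genes, median log2 0.91, adjusted p = 1.0e-17, and 0.00295 with an estimated correlation), 6 of its 10 members passed on their own and 9 when adjusted over the list alone. The light-responsive clock repressor Per1 stood at 32.2 ± 7.18 CPM in males and 14.4 ± 3.87 CPM in females (log2 1.13 ± 0.19, edgeR adjusted p = 9.7e-04, chromosome 11, 69095217 to 69109960). The repressors Nr1d2 (66.8 ± 8.47 against 37.8 ± 8.26, 0.82 ± 0.13, 5.0e-04) and Cry1 (37.3 ± 6.70 against 19.2 ± 4.87, 0.94 ± 0.17, 0.00230), Gm129, also named Ciart (22.2 ± 8.98 against 3.90 ± 2.79, 2.47 ± 0.36, 3.8e-04), and the output gene Dbp (33.8 ± 14.1 against 10.4 ± 3.11, 1.66 ± 0.29, 0.00769) were higher in males too. Cry2 passed as well (0.99 ± 0.21, 0.0119). Outside the clock, Mat2a, which makes S-adenosylmethionine (534 ± 78.4 against 382 ± 35.9, 0.48 ± 0.08, 0.00109), and the RNA polymerase III subunit Polr3e (0.79 ± 0.13, 0.00282) were higher, and Asxl3 (-0.82 ± 0.15, 0.00324) and Kdm6a (-0.52 ± 0.10, 0.00353) lower in males. Without female replicate 4 the calls of Dbp (edgeR adjusted p = 0.0516) and Cry2 were lost, and without male replicate 1 that of Cry2 (up to 0.0546).

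**Figure D1:**
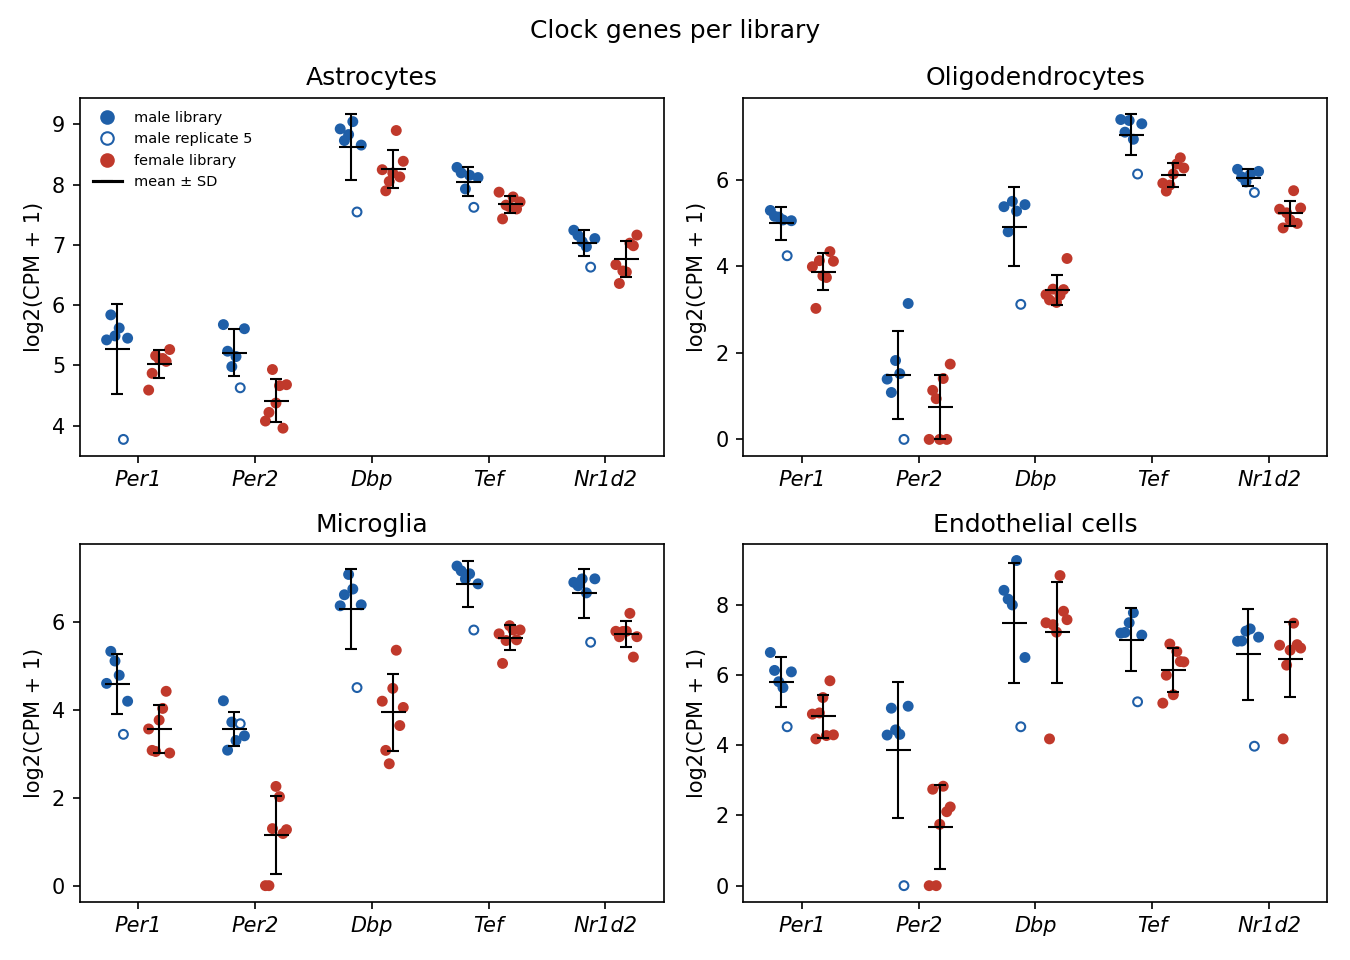
Per1, Per2, Dbp, Tef and Nr1d2 in astrocytes, oligodendrocytes, microglia and endothelial cells, as log2(CPM + 1) on the vertical axis, with 1 point per library, blue for the 6 male and red for the 7 female libraries and black lines for mean ± SD. Male replicate 5 (open circle) stood at 7.72 CPM of Dbp in oligodendrocytes, near the females, but at 11.8 CPM of Per2 in microglia, within the range of the other males.

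In total 22 genes differed in oligodendrocytes, 15 higher and 7 lower in males, of 8422 tested with 656 at an unadjusted p under 0.05, and without male replicate 5 the count was 103. Escape genes were lower in males (5 genes, median log2 -0.34, camera adjusted p = 3.9e-05, and 0.00295 with an estimated correlation). Ribosomal proteins (90 genes, -0.08, 0.00244) and oxidative phosphorylation genes (85, -0.05, 0.00455) were lower, with adjusted p = 0.275 and 0.267 with an estimated correlation. Neuron markers within oligodendrocytes were higher in males (10 genes, median log2 0.37, camera adjusted p = 7.9e-05, and 0.0739 with an estimated correlation).

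Oligodendrocyte precursors differed in 14 genes, 9 higher and 5 lower in males, of 10651 tested (647 at an unadjusted p under 0.05). Hmgcs1, which makes the HMG-CoA used for cholesterol, was higher in males (178 ± 27.9 against 123 ± 14.4 CPM, log2 0.53 ± 0.10, edgeR adjusted p = 0.00127), as was Gpld1, a phospholipase that releases lipid-anchored proteins (268 ± 20.3 against 197 ± 20.2, 0.43 ± 0.08, 0.00161). Kdm6a was lower in males (58.3 ± 9.11 against 94.7 ± 10.9, -0.70 ± 0.12, 1.6e-04). These 3 calls held without any single library, while those of Gfpt2 (0.74 ± 0.16), Cry1 (0.94 ± 0.20), the phagocytosis receptor Mertk (0.53 ± 0.12) and Rlbp1 (-0.31 ± 0.07) were lost without 6, 9, 7 and 9 of them. Ribosomal proteins (93 genes, median log2 -0.08, camera adjusted p = 6.5e-05) and oxidative phosphorylation genes (86, -0.04, 0.0165) were lower in males, with adjusted p = 0.393 and 0.640 with an estimated correlation. Microglia markers (-0.58, 0.0110) were lower and the precursors' own markers (0.05, 0.0142) higher in males, with 0.628 and 0.0924 with an estimated correlation. The count of 14 became 26 without male replicate 5. In newly formed oligodendrocytes Xist, Tsix, Ddx3y and Eif2s3y differed and 0 other genes, with 175 of 4497 at an unadjusted p under 0.05 by edgeR, and DESeq2 and limma voom also called 4 each with the sex-linked list counted. Axon guidance genes (9 genes, median log2 0.29, camera adjusted p = 0.00146) and neuron markers (6, 0.18, 0.0253) were higher and ribosomal proteins (65, -0.11, 2.0e-04) and oxidative phosphorylation genes (78, -0.08, 9.8e-04) lower in males there, with adjusted p = 0.217, 0.561, 0.286 and 0.286 with an estimated correlation.

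In microglia the clock genes again stood higher in males. The list passed camera (7 genes, median log2 0.94, adjusted p = 6.5e-13, and 0.00559 with an estimated correlation), and 4 of its 7 members passed. Tef, a clock-driven transcription factor, stood at 126 ± 35.9 CPM in males and 51.4 ± 8.85 CPM in females (log2 1.27 ± 0.16, edgeR adjusted p = 5.4e-08, chromosome 15, 81802421 to 81826863). Per3 stood at 68.0 ± 26.0 and 21.0006 ± 8.06 CPM (1.67 ± 0.26, 2.4e-04), Nr1d2 at 109 ± 31.6 and 54.6 ± 10.97 (0.98 ± 0.17, 2.0e-04) and Dbp at 90.7 ± 38.8 and 17.6 ± 11.8 (2.31 ± 0.42, 0.0460). The protocadherin-like Fat3 (57.6 ± 14.3 against 19.97 ± 7.13, 1.49 ± 0.21, 1.8e-06), the Ras-like GTPase Mras (1.03 ± 0.17, 3.6e-05), the transglutaminase Tgm2 (0.88 ± 0.16, 6.3e-04), Tspan4 (0.61 ± 0.12) and Dst (0.42 ± 0.09) were higher in males. Lpl, lipoprotein lipase, was lower in males (36.5 ± 14.03 against 89.6 ± 23.3, -1.23 ± 0.20, 1.9e-04). Of these calls that of Dbp was lost without 11 of the 13 libraries, and the others held without any single one. Crlf2 (-0.74 ± 0.17) and the lysosomal protease Ctsl (-0.26 ± 0.06) were lower in males, calls lost without 3 and 11 libraries.

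In total 26 genes differed in microglia, 21 higher and 5 lower in males, of 7458 tested with 540 at an unadjusted p under 0.05, and the count was 47 without male replicate 5. Ribosomal proteins (91 genes, median log2 -0.04, camera adjusted p = 0.00868) and oxidative phosphorylation genes (82, -0.06, 6.9e-05) were lower in males, with adjusted p = 0.545 and 0.162 with an estimated correlation. Neuron markers (9 genes, median log2 0.40, adjusted p = 3.7e-04) and oligodendrocyte markers (8, 0.19, 0.00778) were higher and endothelial markers (8, -1.15, 3.9e-08) lower in males within microglia, with 0.166, 0.148 and 0.148 with an estimated correlation.

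Endothelial cells differed in 66 genes, 54 higher and 12 lower in males, of 5169 tested with 572 at an unadjusted p under 0.05. Slc2a1, the glucose transporter of the blood-brain barrier, stood at 2537 ± 346 CPM in males and 1572 ± 119 CPM in females (log2 0.69 ± 0.10, edgeR adjusted p = 4.1e-06, chromosome 4, 119108711 to 119137983). Mfsd2a, the barrier's lipid transporter (546 ± 63.0 against 365 ± 50.3, 0.60 ± 0.12, 0.00123), Tsc22d3, a glucocorticoid-induced gene (769.7 ± 97.6 against 469 ± 72.5, 0.71 ± 0.11, 1.7e-05), and the BMP receptor Bmpr2 (401 ± 102 against 234 ± 43.0, 0.77 ± 0.14, 3.8e-04) were also higher in males. The same held for Rgs12 (0.76 ± 0.11, 4.2e-06), Gsta4 (0.82 ± 0.14, 5.0e-04), endothelin 3 (Edn3, 0.90 ± 0.16, 0.00123) and the metalloproteinase inhibitor Timp3 (1842 ± 660.0 against 683 ± 89.6, 1.42 ± 0.20, 0.00245). Each of these 8 calls held without any single library. Genes lower in males were the glutathione transferase Gstm7 (-0.87 ± 0.20, 0.00754), Fut8 (-0.70 ± 0.17, 0.0103) and Bsg (12336 ± 2487 against 16199.5 ± 1442, -0.39 ± 0.09, 0.0106). Without male replicate 1 their adjusted p was 0.0769, 0.128 and up to 0.0618, Bsg losing its call also without male replicate 2. Per1 (1.05 ± 0.29, 0.0462) and Tef (0.99 ± 0.25, 0.0462) passed and lost their calls without 9 and 10 libraries.

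The clock list was higher in male endothelial cells (10 genes, median log2 0.57, camera adjusted p = 0.0239, and 0.368 with an estimated correlation), and so were the immediate early genes (15, 0.13, 0.0264, and 0.468). Ribosomal proteins (76 genes, -0.22, 2.6e-11) and oxidative phosphorylation genes (79, -0.14, 3.8e-07) were lower in males, with 0.136 for each with an estimated correlation. Astrocyte markers were higher in males within these cells (6 genes, 0.28, 0.0268, and 0.210). The count of 66 became 36 without male replicate 1 and 136 without male replicate 5. In mural cells Timp3 (3066 ± 708 against 1899 ± 253 CPM, log2 0.69 ± 0.14, edgeR adjusted p = 0.00519) and Fbxo3 (1.32 ± 0.26, 0.00519) were higher in males, beside Xist and Ddx3y, of 3262 genes tested (213 at an unadjusted p under 0.05). The call of Fbxo3 was lost without male replicate 1 (0.0720) and that of Timp3 without male replicates 2 and 6 (up to 0.0609), while the count of 4 became 7 without female replicate 5 and 14 without male replicate 5. Leptomeningeal markers (9 genes, -0.46, 7.9e-06, and 0.145 with an estimated correlation) and ribosomal proteins (57, -0.10, 0.0139, and 0.522) were lower in male mural cells.

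**Figure D2:**
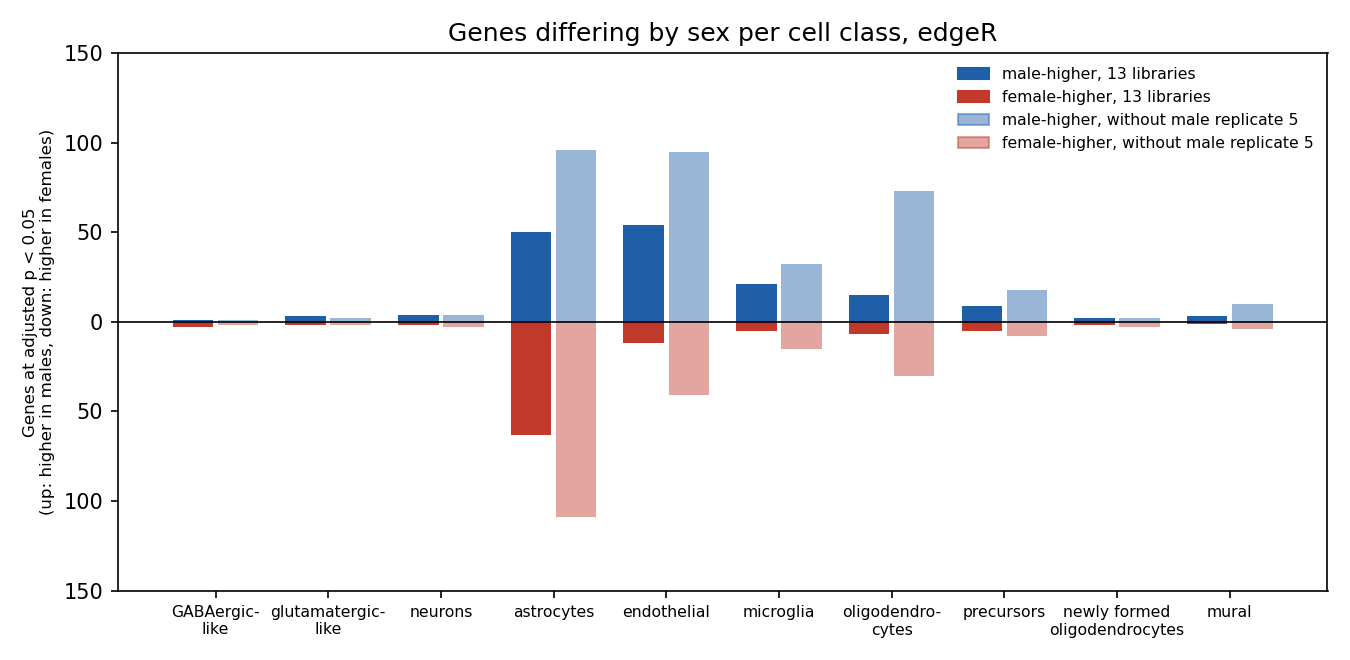
Genes with an edgeR adjusted p under 0.05 in each cell class, upward bars for genes higher in males and downward bars for genes higher in females, in dark colours from 13 libraries and in light colours without male replicate 5. Astrocytes had 50 and 63 such genes and endothelial cells 54 and 12, and all neurons together 4 and 2.

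Over the 7 non-neuronal classes the calls summed to 249, which became 153 without male replicate 1 and 536 without male replicate 5. Outside the sex-linked list 198 genes were called in at least 1 class, with all neurons as 1 class (which had 0 of them), and 14 in more than 1. Of these 14, Kdm6a (astrocytes, oligodendrocytes, precursors), Mertk (astrocytes, precursors, microglia) and Tef (astrocytes, microglia, endothelial cells) were called in 3 classes. The direction was the same in 13 of the 14, and Ahnak was lower in male astrocytes (-0.94) and higher in male endothelial cells (0.44). The classes came from the same 13 libraries, so their calls are not independent. A test of whether the sex difference itself differed between neurons and all other cells called 0 of 13364 genes with edgeR, with 975 at an unadjusted p under 0.05 and a smallest adjusted p of 0.182, and DESeq2 called 0 with 659 at an unadjusted p under 0.05. The neurons in this test included the clusters that glial genes lead. So the larger count of calls in glia and endothelial cells is not a tested difference in effect.

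Clock genes were also followed per library, because a single male library stood apart. The 6 genes Per1, Per2, Per3, Dbp, Tef and Nr1d2 averaged 6.02 to 6.51 log2 CPM over all cells in male replicates 1, 2, 3, 4 and 6, with Arntl, which drives them and whose transcript peaks at the opposite time, at 2.90 to 3.52. The females lay at 5.18 to 5.79 and 3.59 to 4.23 except for female replicate 5 at 6.01 and 2.89, just under the lowest of these males on both measures. Male replicate 5 had 5.43, within the range of the females, and 4.42, above each of them. Average linkage on both measures, set to 2 groups, gave 1 with male replicates 1, 2, 3, 4 and 6 and female replicate 5, and 1 with male replicate 5 and the other 6 females. Within these groups Pearson's r of the 6-gene mean with Arntl was 0.195 (Spearman's rho 0.486, exact permutation p = 0.707 and 0.356, n = 6) and -0.345 (rho -0.357, exact permutation p = 0.444 for both, n = 7). The adjusted p was 0.707 and 0.533 over 6 relations. The groups were formed on the same 2 measures, which narrows their range, so these values cannot speak to whether Arntl runs opposite to the 6 genes. Without the 2 libraries farthest from the median of the 6-gene mean, r was 0.440 and -0.548. Within each sex r was -0.841 in 6 males (rho -0.371, exact permutation p = 0.0764 and 0.497, adjusted p = 0.153) and -0.689 in 7 females (rho -0.393, exact permutation p = 0.113 and 0.396, adjusted p = 0.170). Without the 2 farthest libraries it was 0.440 and 0.341, so in each sex alone the relation rests on those libraries. With both sexes centred on their means, r over 13 libraries was -0.776 (rho -0.593, permutation p = 0.00233 and 0.0368, adjusted p = 0.00699) and -0.5001 without the 2 farthest. Arntl itself stood at 10.9 ± 5.27 CPM in males and 14.8 ± 3.99 CPM in females (log2 -0.44 ± 0.26, edgeR adjusted p = 0.468), and the grouping and these relations were examined after the clock genes had been seen to differ. Nr1d1, a clock repressor, did not follow the other genes: it was lower in males in astrocytes (log2 -0.25 ± 0.10), precursors (-0.42 ± 0.14), endothelial cells (-0.96 ± 0.33) and mural cells (-1.04 ± 0.24) and higher in oligodendrocytes (0.80 ± 0.23). It passed in these classes only when adjusted over the list alone (edgeR adjusted p = 0.0443, 0.0282, 0.0269, 6.0e-04 and 0.00143).

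**Figure D3:**
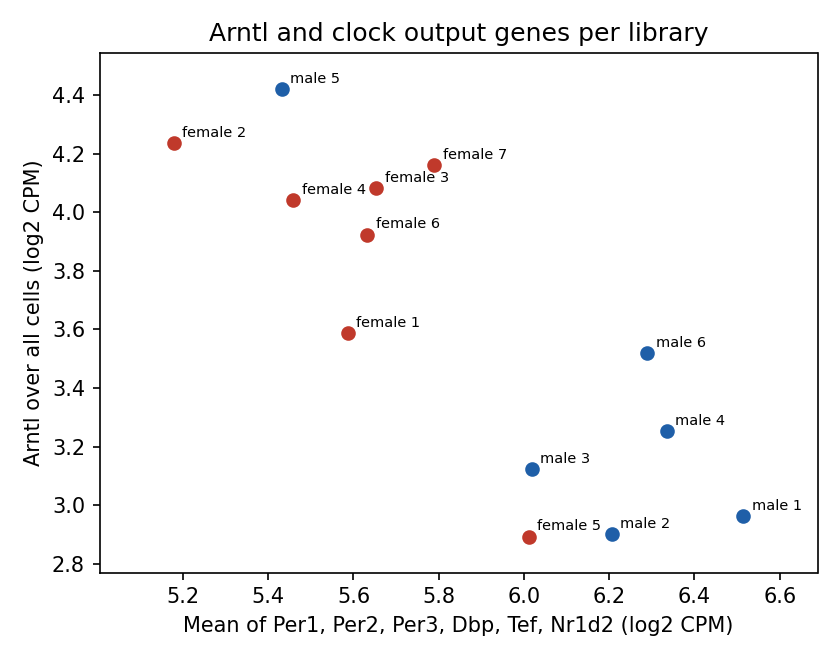
Mean log2 CPM of Per1, Per2, Per3, Dbp, Tef and Nr1d2 (horizontal axis) and log2 CPM of Arntl (vertical axis) over all cells, with 1 labelled point per library, blue for male and red for female. Male replicate 5 (5.43, 4.42) lay nearer to the female libraries and female replicate 5 (6.01, 2.89) nearer to the male ones.

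Cell class shares were compared because the sexes could differ in makeup. Microglia made up 13.6% ± 1.22 of cells in 6 male and 16.5% ± 2.04 in 7 female libraries, a difference of -2.87 percentage points (exact two-sided permutation p = 0.0152, adjusted p = 0.121 over 8 classes). Neurons made up 16.7% ± 3.82 and 13.6% ± 2.95 (exact p = 0.127, adjusted p = 0.254), endothelial cells 5.35% ± 0.932 and 6.46% ± 1.41 (0.125, 0.254), mural cells 2.87% ± 0.502 and 3.35% ± 0.446 (0.0997, 0.254), and astrocytes 27.5% ± 5.29 and 24.7% ± 4.38 (0.315, 0.420), all by the exact permutation test. Oligodendrocytes (15.3% ± 1.49 and 16.2% ± 1.31), precursors (16.7% ± 2.76 and 17.3% ± 2.37) and newly formed oligodendrocytes (1.93% ± 0.628 and 1.85% ± 0.639) had adjusted exact p-values of 0.402, 0.777 and 0.821. So 0 of 8 classes passed the adjusted exact permutation test and 1 had an unadjusted p under 0.05, while without female replicate 2 microglia passed (1 class). Of 17 neuron clusters 0 passed, and clusters 1 (4.78% ± 3.20 against 2.34% ± 1.21 of neurons, exact p = 0.0408) and 6 (5.57% ± 1.60 against 3.72% ± 1.25, exact p = 0.0420) had the smallest p-values, each with an adjusted p of 0.333. Bdnf, a leading gene of cluster 6, itself differed by sex, so the size of that cluster is not read as a difference in cells.

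**Figure D4:**
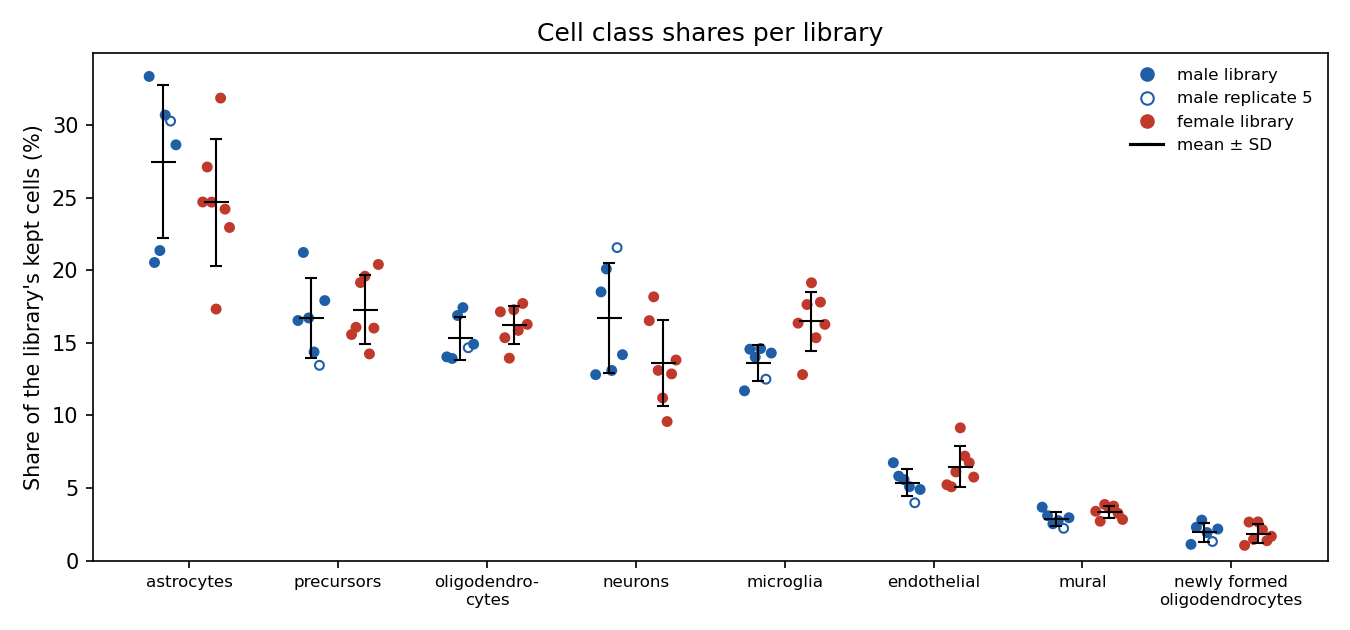
Share of each library's kept cells in each class, in percent, with 1 point per library, blue for the 6 male and red for the 7 female libraries, an open circle for male replicate 5, and black lines for mean ± SD. Microglia averaged 13.6% in males and 16.5% in females, and the points of the sexes overlap in every class.

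Neuropeptide and hormone receptor genes were compared between the neuron classes within the same 13 libraries, with the library as a block. The prolactin receptor Prlr was higher in GABAergic-like than glutamatergic-like neurons (334 ± 106 against 155 ± 68.6 CPM, n = 13, log2 1.137 ± 0.15, edgeR adjusted p = 3.8e-07, higher in 12 of 13 libraries). Cartpt (0.83 ± 0.22, 0.0108), Tac1, the gene of substance P (0.97 ± 0.28, 0.0152), and the granin Chga (0.27 ± 0.09, 0.0178) were higher in GABAergic-like neurons, and Pdyn was higher in glutamatergic-like neurons (-0.76 ± 0.25, 0.0194). Of the 40 genes of both lists 20 were tested, and 18 passed, 13 higher in GABAergic-like and 5 in glutamatergic-like neurons, with 19 when adjusted over the list alone; over all genes 1775 of 4761 passed. Genes that lead a neuron cluster, and so helped to form the classes compared, were Npy (6.23 ± 0.49), Sst (5.41 ± 0.47), Pnoc (4.35 ± 0.23), Ucn3 (3.96 ± 0.66), Nts (3.48 ± 0.44), Vgf (1.16 ± 0.16), Scg2 (0.48 ± 0.12) and Nxph1 (0.46 ± 0.11) toward GABAergic-like, and Trh (-6.03 ± 0.24), Adcyap1 (-4.69 ± 0.15), Cck (-2.87 ± 0.28) and Penk (-0.83 ± 0.15) toward glutamatergic-like neurons. The other genes were not kept out of the clustering. Nr3c1 (-0.27 ± 0.13, 0.0992) and Chgb (-0.10 ± 0.07, 0.274) did not pass.

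**Figure D5:**
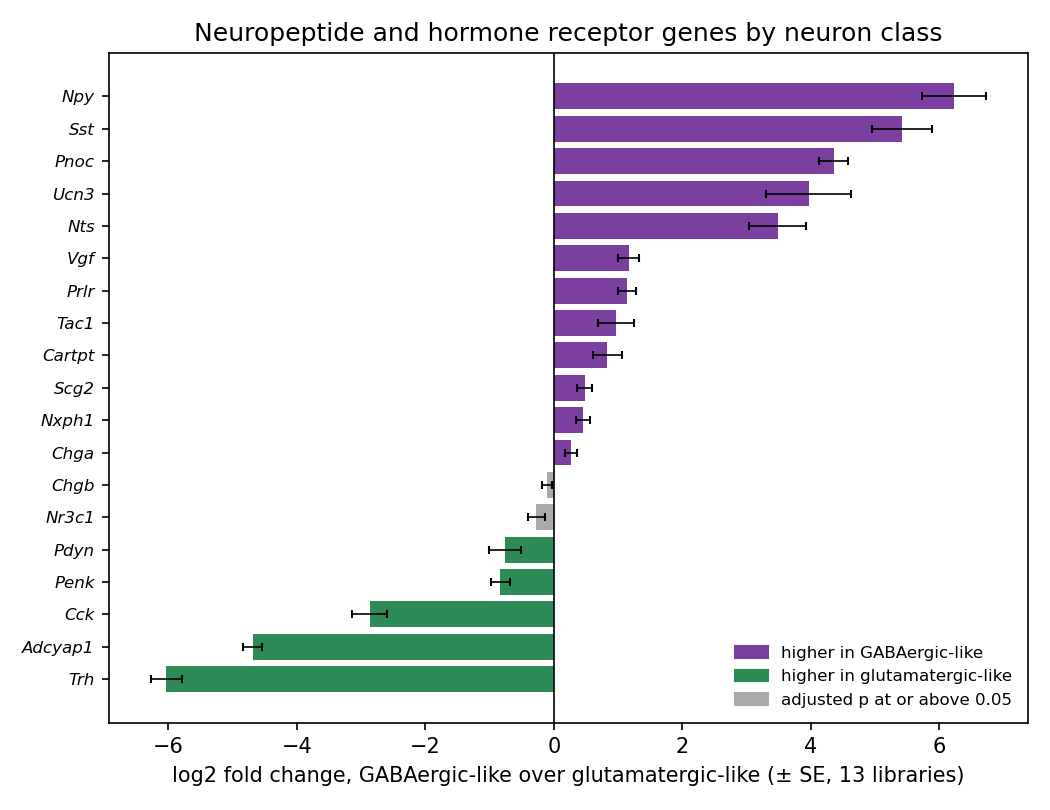
Log2 fold change of GABAergic-like over glutamatergic-like neurons for 19 of the 20 tested neuropeptide and hormone receptor genes (bars, ± SE, 13 libraries), purple where higher in GABAergic-like, green where higher in glutamatergic-like neurons and grey where the edgeR adjusted p was at or above 0.05. The bars run from 6.23 for Npy to -6.03 for Trh.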

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

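The tests of the clock phase, including the grouping of libraries by clock genes, and of equal cell numbers were chosen only after the result was seen; the other tests were set after the patterns had been seen and before their own values were.

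Some libraries stood far from the others of their sex in a single value. Each was the highest or lowest of its group, with a gap to the nearest library that was large for the range of the group. Among 305 groups of values of named genes 28 had such a library, where chance gives 15.25, and 6 of the 28 were in male replicate 5. In male replicate 5, Per1 in oligodendrocytes stood at 18.21 CPM (other males 31.80 to 38.64), Nr1d2 in microglia at 45.83 (97.76 to 127.1), Tspan4 in microglia at 97.64 (172.2 to 207.1), Slc2a1 in endothelial cells at 1626.0 (2241.0 to 2526.0), Kcnk13 in oligodendrocytes at 97.14 (62.81 to 73.99) and Gng11 in oligodendrocytes at 423.3 (286.2 to 332.5). These 6 genes were called between the sexes, and in each the value of male replicate 5 lay toward those of the females.

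Over all cells, male replicate 1 had 44.25 CPM of Cd68 and 74.34 of P2ry13, male replicate 2 had 32.29 of Tspo, male replicate 6 had 54.13 of Rps6ka1, and female replicate 4 had 106.8 of Cd68 and 44.70 of Ocrl. In neurons, Tac1 stood at 1116.0 CPM in female replicate 2 (other females 396.2 to 597.2) and Penk at 407.9 in male replicate 1 (other males 840.7 to 1065.0). Female replicate 3 had 2395.0 CPM of Npy in GABAergic-like and 120.4 of Pdyn in glutamatergic-like neurons, and female replicate 6 had 856.9 of Cck in GABAergic-like neurons. In astrocytes, Xist stood at 1267.0 CPM in female replicate 6, Uty at 36.11 in male replicate 4, Rnft1 at 22.01 in male replicate 1, and Dkk3 at 104.4 and Jund at 126.5 in male replicate 3. Ddx3y stood at 166.0 CPM in oligodendrocytes and 246.0 in endothelial cells of male replicate 4. Female replicate 1 had 355.0 CPM of Tsix in oligodendrocyte precursors and 170.3 in microglia, female replicate 2 had 11.21 of Cry1 in oligodendrocyte precursors, and female replicate 4 had 68.10 of Tgm2 in microglia. Of 50 groups of shares 3 had such a library (2.5 by chance): cluster 1 made up 10.92% of the neurons of male replicate 3, and cluster 6 made up 2.609% and cluster 15 made up 6.957% of those of male replicate 1. Of 8 groups of depth values 1 had one: female replicate 1 kept 1149 cells, where the other females kept 1785 to 2156. No explanation was tested for these single values.

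The sex difference of 2 genes differed between the neuron classes in the test of the class by sex term. The difference was -1.895 on the log2 scale for Gpc3 and -2.578 for Npnt. Among 60 splits of the libraries 1 had as many such genes, the real split itself, and the others had at most 1.

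The clearest pattern was that clock genes stood higher in male oligodendrocytes and microglia, and in part in astrocytes and endothelial cells. It was not a rise of all clock genes, since Nr1d1 was lower in males in astrocytes, precursors, endothelial and mural cells when adjusted over the list alone; what this means for the phase was not tested. Neuron RNA in the droplets of oligodendrocytes is argued against: from neuron markers it brought 0.696% of the male excess of the 6 called clock genes, which summed to 214 ± 42.1 CPM in males and 96.5 ± 16.9 CPM in females. A different daily phase at collection may be a candidate explanation, since the labels give no time of day. It was first tested on Arntl, which cycles opposite to the others, and its fold of -0.4444 (log2, SE 0.258) was within 2 SE of 0. By the rule first written for it such a value counted against the explanation; after the value was seen the rule was changed to leave it undecided, since a value near 0 is not shown to be 0. A second test was added after that: Arntl ran opposite to the 6 output genes over 13 libraries (r = -0.8187, permutation p = 0.00112), and stayed negative when centred within sex (-0.776, permutation p = 0.00233). The test also asked for r below 0 in each sex without the 2 farthest libraries, where it was 0.440 and 0.341. With the changed rule neither test decides. Phase and sex cannot be told apart here unless libraries of both sexes were collected at the same times, and male replicate 5 and female replicate 5, each nearer to the other sex over all cells, are what a difference in collection time within a sex could give. This does not hold for female replicate 5 in oligodendrocytes, where its called clock genes summed to 127 CPM (other females 77.7 to 107, males without replicate 5 at 209 to 247). A stronger glucocorticoid response in males was tested on responsive genes not looked at before, whose median log2 in endothelial cells was 0.2001 (10 genes, p = 0.496 with an estimated correlation). In the classes where the clock pattern was clearest the median was lower, 0.09 in oligodendrocytes (13 genes) and -0.0021 in microglia (7 genes), and it was 0.10 in astrocytes and -0.025 in mural cells. None passed with an estimated correlation, though 11 of 13 genes in oligodendrocytes and 11 of 15 in astrocytes were higher in males. At the preset correlation the unadjusted camera p was 0.00917 in oligodendrocytes and 0.0112 in astrocytes. It was 0.462 in endothelial cells, 0.753 in microglia and 0.426 in mural cells. The responsive genes looked at before were higher in males, with medians of 0.76 in astrocytes, 0.82 in oligodendrocytes, 0.40 in microglia and 0.71 in endothelial cells, and passed there with an estimated correlation. They passed also in neurons (median 0.62), where the clock genes were not called, and in precursors (0.16), but not in mural cells (0.015). However, the values of these genes had been seen before this explanation was tested. So this too stays open. A sex difference of the clock itself also stays open, as untested.

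The genes higher in females over all cells had a median log2 of -0.53, and the class shares of UMIs with 1 fixed profile per class gave a median of -0.35, which is 65.51% of it and in the same direction for 63 of 64 genes. Of the 64, 41 were highest in microglia and 15 in endothelial cells, while 1 and 4 were called within those classes. Microglia gave 9.60% of UMIs in males and 12.7% in females, and endothelial cells 3.80% and 5.38%. These values are consistent with more microglia and endothelial cells in the female libraries. Whether that came from the tissue or from dissection and dissociation was not tested, and the difference in the share of microglia did not pass the adjusted exact permutation test.

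Fewer genes were called in neurons than in astrocytes and endothelial cells. Fewer cells as the whole cause are argued against: at equal cells and UMIs per library, and without the sex-linked genes, 19 genes were called in astrocytes, 33 in endothelial cells and 13 in microglia, and 1 in each neuron class, while oligodendrocytes had 5 and precursors 0. A mixture of neuron types within each class remains open, as untested. Whether the sex difference was other in neurons than in the remaining cells was tested gene by gene, and 0 of 13364 genes passed (smallest edgeR adjusted p = 0.182), which does not show that it was the same.

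The counts of genes were compared with those of other splits of the 13 libraries into groups of 6 and 7, without the sex-linked genes, to ask whether chance alone could give as many. In the real split, and in 1 of 100 splits (the real one itself), 78 genes were called over all cells (highest other 2), 107 in astrocytes (27), 63 in endothelial cells (28), 20 in microglia (4), 7 in oligodendrocyte precursors (4) and 215 over the non-neuronal classes (95). This is the smallest share that 100 splits can give, so chance is unlikely for these 6 counts but not excluded. In oligodendrocytes 2 of 100 splits gave at least the 16 genes, and the other gave 35. That split set male replicate 5 and female replicates 1, 2, 3, 4 and 7 against the other 7 libraries, and the same split gave the highest other counts in astrocytes and endothelial cells. It follows the 2 groups of libraries seen in clock genes except for female replicate 6. This split was picked as the highest and still keeps most libraries on the side of their sex. Whether the samples have a structure apart from sex was thus not tested. A larger share of splits gave as many genes in GABAergic-like neurons (1 gene, 15 of 100 splits, highest other 2), glutamatergic-like neurons (1, 5 of 100, 6), mural cells (2, 6 of 100, 6) and neuron clusters (4, 8 of 56, 10). Chance stays open as the source of these counts. For neuron clusters the splits were drawn over the libraries fitted in each cluster, such as 3 male and 5 female libraries in cluster 4. The splits summed over clusters were thus not the same assignment of libraries in each. Where 0 were called, all splits gave as many: 100 of 100 in all neurons and in newly formed oligodendrocytes (highest other 2 in each), 100 of 100 for the lists in GABAergic-like neurons (6) and 30 of 30 for the term of neurons against other cells (3). For the 18 peptide and hormone genes that differed between the neuron classes, the class of each sample was reassigned within libraries, and 1 of 50 assignments gave as many, the real one, while the others gave 0. The classes were formed by clustering on expression that includes these genes, so this outcome was fixed in advance and says nothing about chance.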

How the results depend on the processing

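The alternatives with cluster 10 and with the parts of cluster 1 were chosen after seeing the data, and the other alternatives were fixed before. Equal cells and UMIs per class was thus fixed before as an alternative. Its use to test the lower counts in neurons was chosen after the result was seen. Of values of named genes 3040 of those without 1 library and 2225 of the others stayed on the same side of the threshold, 397 and 210 no longer passed, 3 and 1 newly passed, and 0 of those that passed in the main analysis reversed (direction was not compared where a gene did not pass). Without 1 library, counts ranged 3 to 5 in GABAergic-like and 4 to 7 in glutamatergic-like neurons, 10 to 234 over all cells, 6 to 9 in all neurons, 64 to 205 in astrocytes, 15 to 103 in oligodendrocytes, 10 to 26 in precursors, 4 to 6 in newly formed oligodendrocytes, 18 to 47 in microglia, 36 to 136 in endothelial cells, 3 to 14 in mural cells, 153 to 536 over non-neuronal classes, 7 to 15 in neuron clusters (5 to 10 of 11 clusters fitted), 1 to 4 for the GABAergic by glutamatergic term, 0 to 1 for class shares and 0 to 1 for lists in GABAergic-like neurons; the term of neurons against other cells and the cluster shares stayed at 0. With no gene filter counts were 8 in GABAergic-like and 10 in glutamatergic-like neurons, 181 in astrocytes, 86 in oligodendrocytes, 9 in newly formed oligodendrocytes, 41 in microglia, 17 in mural cells, 442 over non-neuronal classes, 55 in clusters and 5 for the class by sex term, with more genes tested. In 0 classes did every pair of equal replicate numbers correlate over 0.1, so the numbers were not taken to pair the samples. Correlations were -0.292 to 0.205 over all cells and -0.0685 to 0.254 in astrocytes. Of 12 samples, 1 went best with its own number over all cells and 1 in neurons. The number was 6 in astrocytes, 5 in oligodendrocytes, 5 in microglia, 4 in precursors and 4 in endothelial cells. In each of the latter classes male and female replicate 1 went best with each other. These matches were not tested against chance, so a pairing by number is not excluded. With the replicate number as a block, counts were 7 in GABAergic-like neurons, 14 over all cells, 45 in oligodendrocytes and 43 in endothelial cells. They were 11 in mural cells, 0 for the class by sex term and 1 for the lists. At equal cells and UMIs they were 23 in astrocytes, 8 in oligodendrocytes, 3 in precursors, 16 in microglia, 35 in endothelial cells and 85 in sum over 5 classes, with fewer UMIs. DESeq2 called 350 over all cells, 37 in oligodendrocytes and 0 for the class by sex term, and limma voom 202 over all cells. With age as a covariate counts were 56 over all cells, 36 in oligodendrocytes and 9 in mural cells. With at least 800 genes per cell clusters had 9 (7 fitted). GABAergic-like neurons had 7 with classes from marker UMIs and 7 with the parts of cluster 1. Without the sex-linked genes counts were 1 in each neuron class, 0 in all neurons and in newly formed oligodendrocytes, 7 in precursors, 2 in mural cells and 4 in clusters, by construction. Where no reason is given, the cause was not tested. The mitochondrial filter could not be varied.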

Other observations

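The comparisons of single genes in male replicate 5 and female replicate 5 and of Gad1, Gad2 and Slc32a1 between cell types were chosen only after the result was seen.

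Male replicate 5 stood apart from the other males in several cell types, mostly toward the females. Leaving it out raised the count of genes from 22 to 103 in oligodendrocytes, from 113 to 205 in astrocytes, from 66 to 136 in endothelial cells and from 26 to 47 in microglia. Dbp stood at 7.72 CPM in its oligodendrocytes, where the other males had 26.9 to 44.5 and the females 7.99 to 17.2, and at 22.1 CPM in its endothelial cells, where the other males had 89.7 to 615 and the females 17.2 to 457. Per1 stood at 12.6 CPM in its astrocytes (other males 41.9 to 56.2), below the females at 23.1 to 37.4. Female replicate 5 was the reverse in part: Dbp in its astrocytes stood at 476 CPM, among the males at 402 to 527 without male replicate 5, but in its oligodendrocytes at 9.10 CPM, among the females, and in its microglia at 39.9 CPM, below those males at 81.3 to 134. Both libraries had the sex-linked transcripts of their label, so an exchange of their sex labels is excluded.

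Gad1, which makes GABA, was seen in 16.6% of oligodendrocyte precursors (median depth 2669 UMIs), against 1.21% of astrocytes (1810), 0.695% of oligodendrocytes (3182) and 23.2% of neurons (1755). The transporter Slc32a1 was seen in 39.3% of neurons and 0.559% of astrocytes. The share in precursors thus lay above that in oligodendrocytes, whose cells were deeper.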
